A study of Mus musculus with 34 samples.

How the data were processed

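Total RNA was sequenced from 34 libraries of mouse C127 cells, in 10 groups: 5 lines, each with vehicle and with 100 nM Dex for 2 h. Per the labels' protocols, the endogenous receptor was knocked out, GFP-tagged receptors were introduced, the medium held charcoal-stripped serum before treatment, and libraries were made with a stranded total RNA kit. WT, P631A, W718E and P643A had n = 3 per group and W718S/Y722S had n = 5. The labels name no clones, so a substitution and the line that carries it are not separated by the design. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to mm10 with STAR 2.7.0f and counted with HOMER 4.10.4.

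There were 5 tables, each for 1 line, with 25124 transcripts each. Per the file headers, the authors counted raw reads in exons of RefSeq transcripts, kept 1 transcript per gene and ran the differential expression program of HOMER. The header gives no strand option, so reads of a gene and of an overlapping antisense gene are not separated. The library columns hold log2 values that the authors normalised within each table. Their transform is not named in the file headers. The authors also deposited a log2 fold change, a p-value and an adjusted p-value per gene for Dex against vehicle, without naming the test. Libraries had 24.0 to 43.1 M total reads per the file headers. The exon share was 68.5 to 76.0%, with an exon count of 16.5 to 31.5 M (median 23.9 M). The ribosomal precursor Rn45s took 9.94 to 18.3% of exon counts, and WT lay apart from every mutant line. Its share was 9.94 to 11.4% in WT libraries, 13.8 to 15.4% in P631A and 15.2 to 16.7% in W718E. In P643A it was 15.1 to 15.9% and in W718S/Y722S 15.6 to 18.3%. Whether this split bears on the comparisons with WT was not tested.

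The deposited log2 values were found to be shrunken toward the mean of each gene, to a different degree in each table. Read counts were recovered from them by fitting the shrinkage of each table and rounding, and the fit was checked on the file. Among genes with a mean under 100, between 99.9788 and 100% of the recovered values lay within 0.1 of a whole number. A constant of the fit was itself chosen to make low counts whole, so this check is partly built in. For means of 100 to 1000 the share was 50.3 to 61.3%, so single counts there are approximate. Over all genes with a mean of at least 100, log2 fold changes from the recovered counts had a median absolute difference of 0.000966 to 0.00132 from those of the authors. Most of these genes did not respond to Dex. The gap was larger for strong responders, as in WT for Sgk1 (4.03 here and 3.95 by the authors) and Ccn2 (4.26 and 4.19). Over the genes the authors called, the slope of the deposited change on the recovered change was 0.46 in WT, 0.336 in P631A, 0.307 in W718E, 0.363 in P643A and 0.387 in W718S/Y722S. Levels, log2 changes and folds in the report come from recovered counts divided by the size factors of each table, with a pseudocount of 1 on the log2 scale.

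Dex was compared with vehicle within each line by limma 3.58.1 (lmFit, then eBayes with a variance trend) on the deposited log2 values, in R 4.3.3. Genes with a value of at least 10 on the unlogged scale, in at least as many libraries as the smaller group holds, were tested, and an adjusted p under 0.05 by the Benjamini-Hochberg method was called. Each mutant was compared with WT by the contrast of the changes with Dex in limma over 4 group means. A constant factor between tables cancels in this contrast, and levels were not tested across tables. The 4 differences share the WT libraries.

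The plan written before the data were examined put the differences and the responder sets on the deposited values. They were moved to log2 of the recovered counts plus 1 after the data were seen, for a stated reason. In simulated tables of P631A and WT with the same folds in both, the deposited scale called a difference in 26 of 50 genes at 4-fold, 7 of 50 at 2-fold and 2 of 50 at 1.5-fold, and the recovered scale in 0 of 50 at each. The counts on the deposited values are printed beside those reported. The lines, groups, tests within a line, gene lists, naming rule and most alternatives were fixed before the data were examined.

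The recovery of counts, the calls with Dex in WT, P631A and W718S/Y722S and the difference of P631A and WT were tested on simulated data with known folds in 50 genes per size. The list tests, responder sets, overlaps, the blocked fit and the other differences were not simulated. The simulated counts were negative binomial, with the spread of every gene on the fitted trend of its table. They held no outlying and no near-identical libraries, which the real tables do, so the detection given here may not hold in the real data. For Dex in WT, limma on the deposited scale called 34 of 50 genes at 1.25-fold, 40 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 6 of 12452 unchanged genes called. The same numbers were 32, 40, 44 and 50 for P631A and 41, 43, 50 and 50 for W718S/Y722S. For the difference of P631A and WT on recovered counts they were 18 of 48, 35 of 49, 48 of 49 and 46 of 49, with 6 of 12824 unchanged genes called.

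Named genes passed the test, had a mean of at least 20 normalised counts and had all Dex libraries on the same side of all vehicle libraries. Predicted and unnamed loci were left out. The 12 largest rises and 12 largest falls in WT, and 5 of each in every mutant, were ranked by the change in the deposited values. For the differences, 5 in each direction were ranked without the condition on sides. Members of the gene lists were named besides these. Some genes that the rule names are not reported here, and they were also left out of the screen of single libraries; counts of genes and list tests include every measured gene.

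There were 15 gene lists: GR-induced targets, inflammatory and AP-1/NF-kB genes, circadian clock, interferon-stimulated genes, ERK/MAPK feedback, TGF-beta and matrix, G2/M, ATF4 and ER stress, heat shock and receptor chaperones, cholesterol synthesis, steroid receptors and coregulators, Kruppel-like and early transcription factors, markers of other cell types, RNA quality, and housekeeping. They were tested with camera in limma (preset correlation 0.01, adjusted over lists within a line), and again with a correlation estimated from the data. Responder sets held genes called with the same sign in at least 2 of the 3 mutants other than the one compared, and were tested with fry in limma, adjusted over the 8 sets of the 4 mutants. They used the calls of W718E without its block, and with the block as an alternative chosen after the data were seen. Overlaps of calls were set beside the number that independent lists of the same sizes share.

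Replicate numbers were checked for pairing by the correlation of deviations from group means over genes with a mean of at least 100. In W718E the correlations of same-numbered libraries were 0.106 to 0.586, all above the limit of 0.1 set for pairing, and the blocked values stand beside the unblocked ones. The pairing comes from the data, since the labels do not say what a number shares, and it is uncertain. Of the vehicle libraries of W718E, 2 of 3 correlated best with their own number, as in WT and P643A. In WT, P631A, P643A and W718S/Y722S at least 1 correlation was below the limit.

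Alternatives were other values, filters, normalisations and thresholds, a fit of all 34 libraries, a replicate block, and leaving out each library in turn. Count tests of DESeq2 or edgeR, planned for the case that reads could be recovered, were not run by this work although that case was met. The deposited unit is log2, so the test stated for it was used, and voom in limma on the recovered counts was run beside it. Other work used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not analysed here.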

Results

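RNA sequencing was used to ask how substitutions in the ligand-binding domain of the glucocorticoid receptor (GR), a hormone-activated transcription factor, change which genes a cell switches on or off when hormone is added. The series concerns how GR molecules assemble into multimers. The cells were C127, a mouse adenocarcinoma line, with the endogenous receptor knocked out and a GFP-tagged mouse GR introduced in its place. The lines carried WT receptor, the single substitutions P631A, W718E and P643A, or the double substitution W718S/Y722S. Each line was sampled with vehicle and after 2 h in 100 nM dexamethasone (Dex), a synthetic glucocorticoid. The 34 libraries formed 10 groups, with n = 3 per group in 4 lines and n = 5 per group in W718S/Y722S. Total reads per library ranged from 24.0 to 43.1 M with a median of 32.3 M, and 16.5 to 31.5 M of them were counted in exons. Levels are normalised read counts, mean ± SD over libraries. Each line had a table normalised on its own, so levels set side by side across lines are on separate scales except where size factors over all libraries are named. Changes with Dex were tested between lines, and levels were not. The labels do not say that replicates came from separate cultures, so p-values measure the spread between libraries, which may be technical.

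The receptor transcript was checked first. Nr3c1, the gene that encodes GR (chromosome 18, 39410545 to 39489776 in mm10), was abundant in every group. In vehicle its level was 7457 ± 66.8 in WT, 6756 ± 217 in P631A, 5367 ± 88.2 in W718E, 6132 ± 63.2 in P643A (n = 3 each) and 5302 ± 23.9 in W718S/Y722S (n = 5). With size factors computed over all libraries together, the vehicle level was 85.6% of the WT level in P631A, 72.8% in W718E, 78.3% in P643A and 89.9% in W718S/Y722S. Reads of the introduced receptor and of any transcript left from the disrupted gene both count to Nr3c1, so its level does not measure the introduced receptor alone. With Dex the log2 change was -0.08 ± 0.03 (± SE) in WT, with an adjusted p of 0.0884, and the test of Nr3c1 in WT passed without Dex replicate 1 (adjusted p = 0.0197). Nr3c1 in W718S/Y722S fell from 5302 ± 23.9 to 4982 ± 102 (adjusted p = 0.0474), a call that ended when any library other than Dex replicate 1 was left out, with adjusted p from 0.0540 to 0.118. The changes in P631A, W718E and P643A were 0.02 ± 0.04, 0.00 ± 0.03 and 0.01 ± 0.03, and none passed.

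In cells with WT receptor, Dex raised a set of classical glucocorticoid targets within 2 h. Sgk1, a kinase named for its induction by serum and glucocorticoid, rose from 895 ± 13.2 to 14623 ± 343 normalised counts (n = 3 each), a 16.3-fold change. Per1, a clock repressor, rose from 351 ± 29.0 to 3346 ± 66.8 (9.53-fold), and Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose from 707 ± 33.0 to 4257 ± 138 (6.01-fold). The decreases were smaller. Plk2, a polo-like kinase, fell from 3353 ± 156 to 1598 ± 29.6, Phlda1, a pleckstrin homology-like protein, fell from 1756 ± 67.5 to 833 ± 24.4, and Dusp4, a phosphatase of MAP kinases, fell from 2841 ± 93.4 to 1536 ± 46.5.

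Of 12626 genes tested in WT, 846 passed an adjusted p of 0.05 in limma, 500 higher and 346 lower with Dex. The median log2 change was 0.32 among the genes that rose and -0.22 among those that fell, and 62 rises and 5 falls reached 2-fold. The authors' deposited results gave 616 genes an adjusted p under 0.05, 389 higher and 227 lower, and 607 of them were also called here with the same sign. Dex replicates 2 and 3 of WT differed little from each other (chi-square per gene 1.44, against 7.13 and 6.76 for the other pairs of WT Dex libraries), and these libraries enter all 4 differences from WT. Among the 12 named rises, Ccn2, a matrix-associated growth factor, changed by 4.26 ± 0.08 on the log2 scale (± SE) from a low vehicle level of 79.5 ± 10.1. Arrdc2, an arrestin-domain gene, rose by 3.40 ± 0.07, and Spsb1, an adaptor of a ubiquitin ligase, by 3.16 ± 0.05. Fkbp5, a co-chaperone that lowers hormone binding by GR, rose by 1.71 ± 0.04, and Errfi1, a feedback inhibitor of the EGF receptor, by 2.26 ± 0.06. Bcl2l1, which encodes the survival factor BCL-XL, rose from 2623 ± 80.5 to 7734 ± 146, and Glul, glutamine synthetase, from 3099 ± 80.4 to 8506 ± 204. Slc39a14, a zinc and iron transporter, rose by 1.39 ± 0.03, and Tsku, a secreted leucine-rich repeat protein, by 1.67 ± 0.04. Among the 12 named falls, Ankrd1, an ankyrin repeat protein of the nucleus, changed by -0.73 ± 0.03, Gdnf, a neurotrophic factor, by -0.77 ± 0.05, and Btg1, an antiproliferative gene, by -0.52 ± 0.03. Gfod1, Frmd6, Plekho2 and Tsc22d2 fell by between 0.59 and 0.48 on the log2 scale. Cpeb4, an RNA-binding regulator of polyadenylation, and Aqp5, a water channel, changed by -0.45 ± 0.03 and -0.42 ± 0.03. The weakest of these 24 tests, that of Aqp5, had an adjusted p of 1.21e-08.

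In mm10 the RefSeq transcript of Sgk1 spans chromosome 10, 21994666 to 21999902, that of Per1 chromosome 11, 69098949 to 69109957, and that of Tsc22d3 chromosome X, 140539529 to 140548571. Ccn2 spans chromosome 10, 24595442 to 24598682, Arrdc2 chromosome 8, 70835138 to 70839720, Spsb1 chromosome 4, 149896284 to 149955006 and Fkbp5 chromosome 17, 28398753 to 28486149. Plk2 spans chromosome 13, 110395044 to 110400843, Phlda1 chromosome 10, 111506286 to 111508649 and Dusp4 chromosome 8, 34807610 to 34819894. The counts are of exonic reads over the whole transcript.

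**Figure D1:**
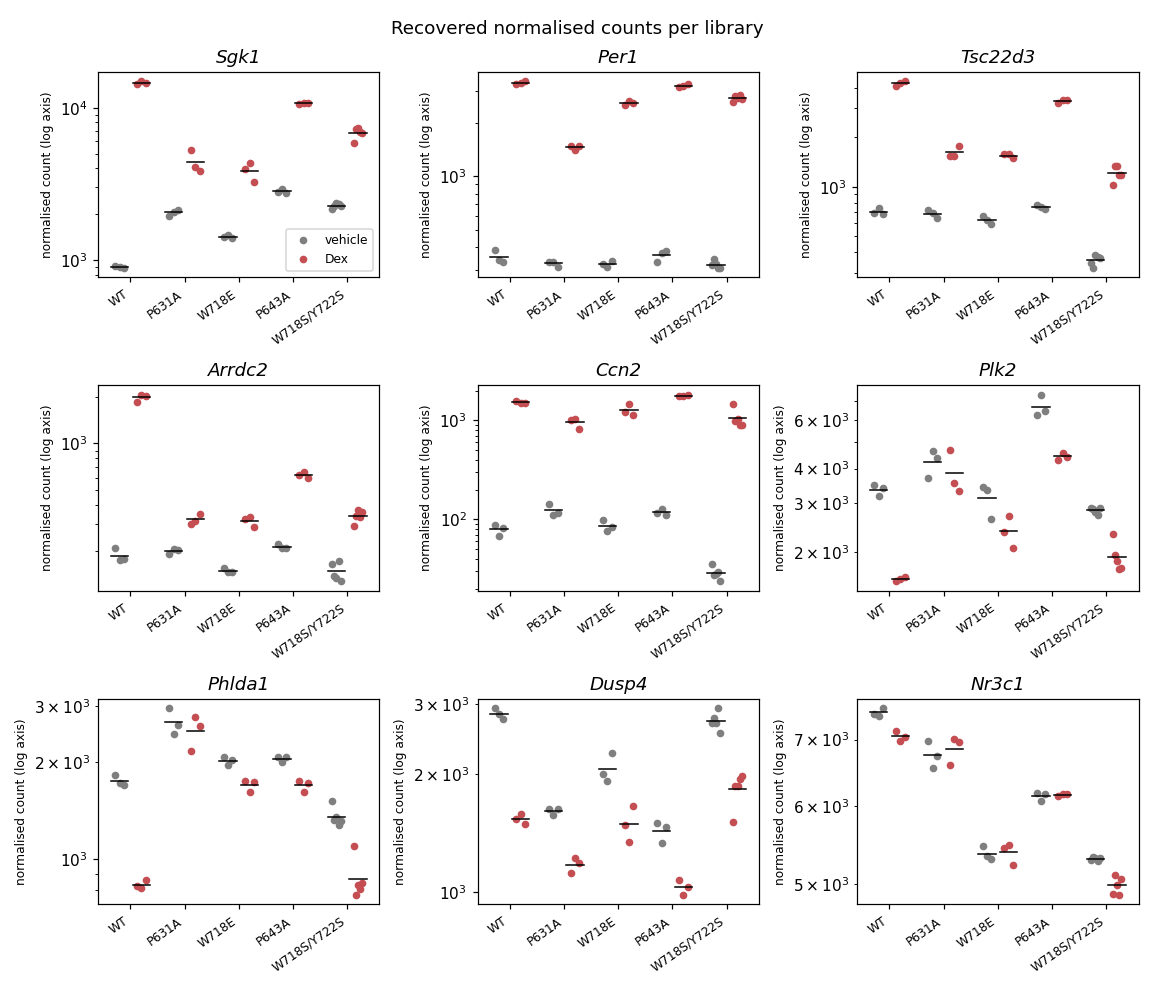
Normalised read counts (log axis) of 8 Dex-responsive genes and of Nr3c1 in each library, vehicle in grey and Dex in red, with a bar at each group mean; n = 3 per group and n = 5 in W718S/Y722S. Levels are set within each line's own table. Sgk1 rose 16.3-fold in WT and 2.14-fold in P631A, while Per1 rose 9.53-fold and 4.47-fold.

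The gene lists fixed before the data were examined behaved as follows in WT. Of 21 measured members of the GR-induced list, 20 rose and 1 fell, and the counts adjusted over the list alone were the same, 20 and 1. Besides the genes above they included Klf9, a Kruppel-like factor (1005 ± 55 to 1543 ± 39.7), Cebpd, a leucine zipper factor (253 ± 11.8 to 496 ± 26.6), Mt1, a metallothionein (0.92 ± 0.04 on the log2 scale), and Lcn2, an iron-trafficking lipocalin (4.69 ± 0.32). The member that fell was Lpin1, a phosphatidate phosphatase (-0.17 ± 0.04). The list passed the set test with a preset correlation and also with an estimated one (adjusted p = 0.000863). Of 18 inflammatory and AP-1/NF-kB genes 8 fell and 1 rose, against 10 and 1 adjusted over the list alone. The chemokine genes Ccl2 (341 ± 25.9 to 226 ± 10.3) and Ccl7 (247 ± 37.0 to 162 ± 7.09) fell, as did the AP-1 gene Fosl1 (451 ± 43.5 to 287 ± 10.8) and the growth factor gene Csf1. The member that rose was Tnfaip3, an inhibitor of NF-kB signalling (218 ± 16.9 to 413 ± 2.27). That list passed the set test (adjusted p = 7.03e-06), and not with an estimated correlation (adjusted p = 0.0549 with an estimated correlation).

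Feedback regulators of ERK/MAPK signalling moved down in WT. Of 15 measured, 6 fell and 0 rose, against 8 and 0 adjusted over the list alone, and the list passed with an estimated correlation too (adjusted p = 0.0195). Spry1, an inhibitor of receptor tyrosine kinase signalling, fell from 466 ± 11.4 to 318 ± 24.5, and Ier3, an early response gene, from 675 ± 78.4 to 438 ± 21.2, beside Dusp4 and Phlda1. Of 16 clock genes 6 rose and 2 fell, against 6 and 4 adjusted over the list alone. Per2 (538 ± 45.2 to 1199.7 ± 10.4), Nfil3 (417 ± 26.9 to 862 ± 41.9) and Bhlhe41 rose with Per1, and Bhlhe40 and Arntl fell. The clock list passed the set test (adjusted p = 0.0028) and lost the call with an estimated correlation (adjusted p = 0.0841 with an estimated correlation). Its median log2 change was 0.01 and its mean 0.36. Of 20 Kruppel-like and early transcription factors 7 rose and 4 fell, against 9 and 5 adjusted over the list alone. Id1, an inhibitor of bHLH factors, rose from 183 ± 10.48 to 434 ± 41.5, while Klf4 fell from 787 ± 36.9 to 454 ± 38.6 and Myc from 1555 ± 30.7 to 1164 ± 8.09. The set test of this list gave an adjusted p of 0.0308 (adjusted p = 0.167 with an estimated correlation). Of 20 cholesterol synthesis genes 4 fell and 0 rose, both over all genes and adjusted over the list alone. Sqle, squalene epoxidase, was among those that fell, and Insig1, a sterol sensor, fell from 14229 ± 154 to 11403 ± 679. That list had an adjusted p of 0.0064 (adjusted p = 0.357 with an estimated correlation).

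Of 21 TGF-beta and matrix genes 5 rose and 3 fell (6 and 4 adjusted over the list alone). Smad7, an inhibitor of TGF-beta signalling, fell from 877 ± 3.37 to 618 ± 14.0. The mean of the list was 0.30 on the log2 scale, and it did not pass the set test (adjusted p = 0.362). Of 19 ATF4 and ER stress genes 2 rose and 2 fell, and of 19 heat shock and receptor chaperone genes 2 rose and 0 fell, with the same counts adjusted over each list alone. Neither list passed (adjusted p = 0.270 and 0.106). Of 17 steroid receptor and coregulator genes only Nr3c2, the mineralocorticoid receptor gene, rose (16.1 ± 3.95 to 31.8 ± 5.03). No member of the G2/M list (20 measured), the interferon-stimulated list (12 measured) or the housekeeping list (15 measured) passed, over all genes or adjusted over the list alone. The G2/M list nevertheless passed the set test downward with a median log2 change of -0.07 (adjusted p = 0.00635), a call lost with an estimated correlation (adjusted p = 0.592 with an estimated correlation). Of 8 measured markers of other cell types 1 rose (2 adjusted over the list alone). This was Fabp4, a fatty acid carrier of adipocytes and macrophages, which went from 5.99 ± 3.38 to 79.5 ± 11.1. Among 5 measured RNA quality transcripts Rn45s, the multi-copy ribosomal RNA precursor, fell on the deposited values (adjusted p = 0.0130; 1 higher and 1 lower adjusted over the list alone). Its log2 change was -0.13 ± 0.08 on the recovered counts, where it did not pass (adjusted p = 0.509), so this call is uncertain.

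With the P631A receptor few genes were called with Dex, in libraries noisier than those of WT. Over genes with a mean of at least 100, the median residual SD (log2) was 0.0687 in P631A and 0.0531 in WT. It was 0.0637 in W718E, 0.0516 in P643A and 0.0701 in W718S/Y722S. More noise lowers the power to call a gene, so counts of calls do not measure the breadth of a response alone. Per1 rose from 324 ± 11 to 1453 ± 46.9 (n = 3 each), a 4.47-fold change, and Ccn2 from 124 ± 17.3 to 955 ± 114 (7.68-fold). Sgk1 rose from 2049 ± 106 to 4422 ± 776 (2.14-fold), Tsc22d3 2.34-fold and Tsku 1.57-fold. Fkbp5, Glul and Errfi1 had log2 changes of 0.17 ± 0.05, 0.02 ± 0.04 and 0.19 ± 0.07 and did not pass. Of 12691 genes tested 28 passed in limma, 25 higher and 3 lower, and 712 had an unadjusted p under 0.05. Of the rises 6 reached 2-fold. The 3 genes that fell were Dusp4 (-0.46 ± 0.05), Irs1, an insulin receptor substrate (-0.26 ± 0.05), and Rprl3, an RNase P RNA-like gene (-0.55 ± 0.07). Reads of Rprl3 may be shared with other copies of that RNA, so its level is uncertain. The authors' deposited table called 39 genes, 33 higher and 6 lower, and all 28 calls made here were among them.

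Of 19 measured GR-induced genes 6 rose in P631A, against 11 adjusted over the list alone, and none fell. They included Klf9 (660.2 ± 75.3 to 910.3 ± 41.1), Ampd3, an AMP deaminase (0.36 ± 0.05 on the log2 scale), and Ddit4, an inhibitor of mTORC1 (0.29 ± 0.05). The list passed with an estimated correlation (adjusted p = 0.00409). Of 15 ERK/MAPK feedback genes 1 fell, Dusp4, with 1 also when adjusted over the list alone, and the list passed the set test (adjusted p = 0.000364 with the preset value, adjusted p = 0.199 with an estimated correlation). Of 16 clock genes Per1 alone rose (3 rose and 1 fell adjusted over the list alone), and the list's adjusted p was 0.0253 (adjusted p = 0.199 with an estimated correlation). Of 17 inflammatory genes none passed, over all genes or adjusted over the list alone, and Ccl2 went from 131 ± 24.0 to 121 ± 36.1. The number of calls rested on single libraries. It was 17 without vehicle replicate 2, 14 without vehicle replicate 3, 49 without Dex replicate 1 and 15 without Dex replicate 2. Irs1 in P631A lost its call when any library other than Dex replicate 1 was left out, with adjusted p from 0.0607 to 0.311.

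The Dex response of P631A differed from that of WT, by a test of the difference itself, in 252 of 13089 genes, 187 with a lower and 65 with a higher log2 change in the mutant. On the deposited values the count was 345, and 248 genes were called on both. Of the 252, 241 were also called in WT, and all of these had a smaller or opposite change in the mutant, of opposite sign in 82. This sign is that of the estimate, here and for each other mutant, and the change in the mutant may lie near 0. Among genes tested in both lines, 0 were called in opposite directions in P631A and WT. The WT libraries both called the 241 genes and entered the difference. This choice of genes thus favours a smaller change in the mutant, here and for each other mutant. The difference (mutant minus WT, log2 ± SE) was -2.93 ± 0.11 for Sgk1, -2.72 ± 0.11 for Arrdc2 and -2.46 ± 0.10 for Spsb1. Lcn2 (-3.79 ± 0.62) and Fabp4 (-2.75 ± 0.40) were also lower. With size factors over all libraries, Sgk1 was at 1833 ± 94.5 in P631A and 848 ± 9.39 in WT in vehicle, and at 3952 ± 685 and 13801 ± 408 with Dex. Fabp4 was at 23.9 ± 1.79 and 5.67 ± 3.18 in vehicle, and at 45.7 ± 11.4 and 75.1 ± 10.8 with Dex. Per1, with its 4.47-fold rise, still differed from WT by -1.09 ± 0.08 (adjusted p = 1.55e-08). The falls of WT were missing or smaller in the mutant for Phlda1 (0.98 ± 0.10), Gdnf (0.93 ± 0.08), Plk2 (0.93 ± 0.13), Plau, a urokinase (0.86 ± 0.14), and Rnd1, a small GTPase (0.78 ± 0.15), none of which passed in P631A. The difference passed for 14 of 21 GR-induced genes, all with the smaller rise in the mutant, and for 3 of 15 ERK/MAPK feedback genes, Dusp4, Ier3 and Phlda1. Among the 11 genes not called in WT were Lars2, a mitochondrial leucyl-tRNA synthetase, and the RNase P and MRP RNAs Rpph1, Rprl3 and Rmrp.

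With the W718E receptor Per1 and Ccn2 rose strongly while most other targets rose little. Per1 went from 322 ± 14.1 to 2577 ± 74.2 (7.99-fold, n = 3 each) and Ccn2 from 86.2 ± 11.4 to 1273 ± 175 (14.6-fold). Sgk1 rose from 1413 ± 32.7 to 3843 ± 544 (2.7-fold), Tsc22d3 2.45-fold and Tsku 2.30-fold. Dusp4 (-0.46 ± 0.08 on the log2 scale), Phlda1 (-0.25 ± 0.04), Thbs1, a matrix glycoprotein (-0.20 ± 0.03), Bdnf, a neurotrophin (-0.29 ± 0.05), and Rprl3 (-0.31 ± 0.05) fell. Of 12598 genes 66 passed in limma, 60 higher and 6 lower, and 738 had an unadjusted p under 0.05. With the replicate number as a block the count was 288. For Dex against vehicle in W718E, genes higher then numbered 167, and for Dex against vehicle in W718E, genes lower numbered 121. In this line same-numbered libraries deviated together, so the blocked value stands beside the unblocked one. The authors' deposited table called 77 genes, 65 higher and 12 lower, and 65 calls were shared with the same sign. Without vehicle replicate 1 the count was 28, and without Dex replicate 1 it was 42. The calls of Dusp4 in W718E (adjusted p 0.0957 and 0.112), Phlda1 in W718E (0.177 and 0.0707) and Thbs1 in W718E (0.147 and 0.112) ended without vehicle replicate 1 and without Dex replicate 1. Rprl3 in W718E lost its call without vehicle replicate 1 (0.0843), Phlda1 also without Dex replicate 2 (0.0864), and Bdnf in W718E when any library other than vehicle replicate 3 was left out (0.0607 to 0.242).

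Of 20 measured GR-induced genes 8 rose in W718E and none fell, against 15 and 1 adjusted over the list alone, and the list passed with an estimated correlation (adjusted p = 0.00263). These counts are without the block. With the block Ampd3 was called as well, and the list's adjusted p in camera was 0.0490 with an estimated correlation. Fkbp5 rose from 2103 ± 248 to 2700.2 ± 145, Glul from 2866 ± 207 to 3479.5 ± 144 and Klf9 from 610.4 ± 56.2 to 1029.6 ± 42.3. Of 16 clock genes 3 rose, Per1, Per2 (597 ± 33.5 to 852 ± 57.1) and Bhlhe41, with 3 adjusted over the list alone, and the set test gave an adjusted p of 0.0202 (adjusted p = 0.16 with an estimated correlation). Of 20 TGF-beta and matrix genes 2 rose and 1 fell, the same adjusted over the list alone, with an adjusted p of 0.00958 (adjusted p = 0.16 with an estimated correlation). The RNA quality list passed downward although none of its 5 members did (0 and 2 adjusted over the list alone). Rmrp went from 50745 ± 1341 to 37185 ± 6909 and Rpph1 from 104056 ± 4635 to 91538 ± 2843, and the list's adjusted p was 0.000134 (adjusted p = 0.16 with an estimated correlation). With the replicate block 3 further lists passed, the inflammatory list (adjusted p = 0.00992), the ERK/MAPK feedback list (0.0157) and the Kruppel-like and early factors (0.0441). These calls were lost with an estimated correlation in the blocked fit (adjusted p = 0.2502, adjusted p = 0.2502 and adjusted p = 0.331). Without the block none of the 17 inflammatory genes passed, and 2 of 15 ERK/MAPK feedback genes, Dusp4 and Phlda1, fell.

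The response of W718E differed from that of WT in 230 of 13041 genes, 166 lower and 64 higher in the mutant. The count was 370 with the replicate block and 357 on the deposited values. Of the 230, 219 were called in WT, each with a smaller or opposite change in the mutant, of opposite sign in 48 by the estimate. Among genes tested in both lines, 0 were called in opposite directions in W718E and WT without the block. With it, 1 gene was called higher in W718E and lower in WT, and 0 the reverse. As in P631A, choosing genes by their WT call favours a smaller change in the mutant. Among the 11 genes not called in WT were Rmrp, Rprl3 and Rpph1, with differences (log2 ± SE) of -0.63 ± 0.13, -0.37 ± 0.07 and -0.27 ± 0.07. The difference (log2 ± SE) was -2.60 ± 0.09 for Sgk1, -2.33 ± 0.11 for Arrdc2, -2.04 ± 0.12 for Spsb1, -2.92 ± 0.53 for Lcn2 and -2.58 ± 0.41 for Fabp4. Tsc22d3 (-1.29 ± 0.07), Fkbp5 (-1.35 ± 0.09) and Errfi1 (-1.77 ± 0.08) also differed. With size factors over all libraries, vehicle levels in W718E and WT were 1355 ± 31.9 and 848 ± 9.39 for Sgk1, 569 ± 27.0 and 295 ± 27.3 for Errfi1, and 18.3 ± 2.61 and 5.67 ± 3.18 for Fabp4. With Dex they were 3680.4 ± 515 and 13801 ± 408, 800.0 ± 17.3 and 1408 ± 19.4, and 39.4 ± 8.31 and 75.1 ± 10.8. For Per1 the difference was -0.25 ± 0.07 (adjusted p = 0.131) and for Ccn2 -0.39 ± 0.15 (adjusted p = 0.389), and neither passed, although on the deposited values both did (adjusted p = 8.69e-11 and 7.08e-07). Phlda1 (0.82 ± 0.06), Ankrd1 (0.71 ± 0.10), Plk2 (0.67 ± 0.12) and Plau (0.72 ± 0.16) had smaller decreases than in WT. Slc41a3, a magnesium transporter of low level, differed by 0.80 ± 0.19 (adjusted p = 0.0317) and not on the deposited values (adjusted p = 0.266). The call of Slc41a3, W718E minus WT, also ended when any library other than WT Dex replicate 1 and W718E vehicle replicate 1 was left out (0.0522 to 0.113). That of Plau, W718E minus WT, ended without WT vehicle replicate 1, WT vehicle replicate 3 or W718E Dex replicate 1 (0.0548 to 0.0646). The difference passed for 11 of 21 GR-induced genes, each lower in the mutant.

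With the P643A receptor a broad set of genes responded. Per1 rose from 361 ± 26.7 to 3222 ± 61.4 (8.91-fold, n = 3 each) and Ccn2 from 117 ± 9.05 to 1785 ± 35.2 (15.1-fold). Sgk1 rose from 2829 ± 84.7 to 10680.1 ± 57.7 (3.78-fold) and Tsc22d3 from 753 ± 23.5 to 3329 ± 77.4. Plk2 fell from 6695 ± 608 to 4427 ± 132, Thbs1 from 65928 ± 3974 to 50051 ± 1191, and Ptgs2, the inducible cyclooxygenase, from 2534 ± 392 to 1689 ± 87.0. Fosl2, an AP-1 subunit, and Irs1 changed by -0.37 ± 0.03 and -0.36 ± 0.03 on the log2 scale. Of 12597 genes 602 passed in limma, 331 higher and 271 lower, of which 30 and 2 reached 2-fold. The authors' deposited table called 408, 253 higher and 155 lower, and 399 were shared with the same sign.

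Of 21 measured GR-induced genes 19 rose and 1 fell in P643A, against 20 and 1 adjusted over the list alone, and the list passed with an estimated correlation (adjusted p = 0.00265). Klf9 rose from 633 ± 8.08 to 1390.3 ± 11.2, a 2.20-fold change, and Fkbp5 from 2503 ± 73.7 to 4080.3 ± 92.1. Of 17 inflammatory genes 2 rose and 2 fell (2 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.443). Cxcl1, a neutrophil chemokine gene, rose from 181 ± 15.1 to 274 ± 8.92 with Tnfaip3, while Ptgs2 and Csf1 fell and Ccl2 went from 174 ± 15.6 to 172 ± 12.3. Of 16 clock genes 5 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.000113, and adjusted p = 0.163 with an estimated correlation). Of 15 ERK/MAPK feedback genes 3 fell, Dusp4, Phlda1 and Spry1, and Dusp7 rose, with the same counts adjusted over the list alone (adjusted p = 0.0334, and adjusted p = 0.571 with an estimated correlation). Of 17 steroid receptor and coregulator genes Kmt2d, a histone methyltransferase gene, and Ppargc1a, a coactivator gene, fell (3 adjusted over the list alone), with an adjusted p of 0.0389 (adjusted p = 0.571 with an estimated correlation). Of 20 Kruppel-like and early factors 8 rose and 6 fell (8 and 6 adjusted over the list alone), without passing as a set (adjusted p = 0.0684). Malat1 and Neat1, nuclear long noncoding RNAs of the RNA quality list, fell (-0.11 ± 0.04 and -0.27 ± 0.07; 2 of 5 measured, 2 adjusted over the list alone), and that list passed downward (adjusted p = 0.0054, and adjusted p = 0.163 with an estimated correlation). Among 10 measured markers of other cell types Fabp4 rose from 56.3 ± 11 to 189 ± 6.92 and Krt14, a basal keratin, fell from 342 ± 25.2 to 285 ± 23.2 (1 and 1 adjusted over the list alone).

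The response of P643A differed from that of WT in 203 of 13067 genes, 127 lower and 76 higher in the mutant, and in 312 on the deposited values. Of the 203, 186 were called in WT. In 178 of these the mutant had a smaller or opposite change, of opposite sign in 38 by the estimate, and in 8 a larger one. Among genes tested in both lines, 3 were called higher in P643A and lower in WT, and 1 the reverse. Choosing genes by their WT call favours a smaller change here too. Sgk1, Arrdc2 and Spsb1 rose less, with differences of -2.11 ± 0.04, -1.87 ± 0.09 and -1.13 ± 0.07 (log2 ± SE). With size factors over all libraries, Sgk1 in vehicle was 2553 ± 76.3 in P643A and 848 ± 9.39 in WT, and with Dex 9607 ± 62.2 and 13801 ± 408. Fkbp5 was 2258 ± 66.2 and 1221 ± 48.1 in vehicle, and 3670.5 ± 84.5 and 3985 ± 129 with Dex. Edn1, the gene of the peptide endothelin, rose in WT with a log2 change of 0.80 and had a change of -0.55 in the mutant that did not pass (adjusted p = 0.230), a difference of -1.35 ± 0.28. Fabp4 differed by -1.89 ± 0.34, and not on the deposited values (adjusted p = 0.764), and on the same scale its level was 50.8 ± 9.94 in P643A and 5.67 ± 3.18 in WT in vehicle, and 170.3 ± 6.29 and 75.1 ± 10.8 with Dex. For Per1 (-0.10 ± 0.07, adjusted p = 0.768) and Ccn2 (-0.34 ± 0.11, adjusted p = 0.158) the difference did not pass, although it did on the deposited values (adjusted p = 1.15e-07 and 4.89e-06). Klf9 had a larger log2 change than in WT, by 0.52 ± 0.06 (adjusted p = 2.56e-06), as did Ccbe1, a secreted lymphangiogenic factor gene, by 0.55 ± 0.06. With size factors over all libraries, Klf9 was lower in P643A than in WT in vehicle (571 ± 7.11 and 952 ± 52.0) and with Dex (1251 ± 11.3 and 1456 ± 45.1). Ccbe1 was at 1233 ± 101 and 1738 ± 81.4 in vehicle, and at 2166 ± 25.03 and 2087 ± 66.8 with Dex. Phlda1 (0.80 ± 0.05) and Plau (0.70 ± 0.13) had smaller decreases than in WT, and Cxcl1 (0.82 ± 0.16), which rose in the mutant, did not pass in WT. Nckap5l differed by 0.79 ± 0.13, with a fall in WT (-0.48 ± 0.05) and a change of 0.30 ± 0.15 in the mutant that did not pass. Lims2, a focal adhesion protein gene at a low level, differed by 1.01 ± 0.24 (adjusted p = 0.0224), and not on the deposited values (adjusted p = 0.110). The call of Lims2, P643A minus WT, ended without WT vehicle replicate 1, WT vehicle replicate 3, WT Dex replicate 2, WT Dex replicate 3 or P643A Dex replicate 3 (0.0510 to 0.0971). Of 21 GR-induced genes the difference passed for 10 with a lower change and for Klf9 with a larger rise.

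With the W718S/Y722S receptor the number of responding genes was close to that in P643A. Ccn2 rose from 28.7 ± 4.45 to 1057 ± 236 (35.3-fold, n = 5 each) and Per1 from 319 ± 14.4 to 2753 ± 94.1 (8.60-fold). Sgk1 rose from 2271 ± 74.5 to 6863 ± 601 (3.01-fold) and Tsku from 2059 ± 74.9 to 5568 ± 949. Thbs1 fell from 16538 ± 973 to 11146 ± 1066, Dusp4 from 2725 ± 144 to 1828 ± 186, Plk2 from 2825 ± 69.3 to 1923 ± 238 and Phlda1 from 1356 ± 91.7 to 871 ± 129.6. Adamts1, a matrix protease gene, fell from 1642 ± 56.9 to 1097 ± 128. Of 12436 genes 596 passed in limma, 317 higher and 279 lower, and 22 rises and 0 falls reached 2-fold. The authors' deposited table called 608, 329 higher and 279 lower, and 560 were shared with the same sign. Dex replicate 1 stood apart from the other 4 Dex libraries, and without it 971 genes were called, including 589 of the 596. With replicates 1 to 3 alone, the size of the other lines, the count was 213, and with the pairs of libraries closest to each other averaged it was 273.

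Of 19 measured GR-induced genes 13 rose and 1 fell in W718S/Y722S, against 15 and 2 adjusted over the list alone, and the list passed with an estimated correlation (adjusted p = 0.000662). Klf9 rose from 635 ± 14.9 to 1193 ± 57.5 and Fkbp5 from 1612 ± 50.2 to 2488 ± 146, and Lpin1 fell from 1089 ± 58.1 to 865 ± 19.2. Of 15 ERK/MAPK feedback genes 4 fell and 1 rose (7 and 2 adjusted over the list alone). Dusp4, Dusp6, Ier3 and Phlda1 fell, and Dusp7 rose from 817 ± 31.7 to 1025 ± 41.1, with an adjusted p of 0.0143 for the list (adjusted p = 0.752 with an estimated correlation). Of 20 cholesterol synthesis genes 4 fell (8 adjusted over the list alone), among them Insig1 (4468 ± 287 to 3435 ± 185), with an adjusted p of 0.000722 (adjusted p = 0.752 with an estimated correlation). Of 19 ATF4 and ER stress genes 3 fell, Chac1, Ddit3 and Trib3, with 3 adjusted over the list alone and an adjusted p of 0.0402 (adjusted p = 0.752 with an estimated correlation). Of 17 inflammatory genes 2 fell, Jun and Ptgs2, and Tnfaip3 rose (4 and 1 adjusted over the list alone), without passing as a set (adjusted p = 0.117). Of 16 clock genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.762), with Per2 rising from 369 ± 28.3 to 573 ± 13.1 and Nr1d1, a heme-binding repressor, falling from 466 ± 23.7 to 377 ± 35. Of 20 Kruppel-like and early factors 6 rose and 8 fell (7 and 9 adjusted over the list alone; adjusted p = 0.603). Of 15 housekeeping genes 1 fell and 14 did not pass (0 rose and 1 fell adjusted over the list alone), and the set test did not pass (adjusted p = 0.678).

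The test of the difference of the Dex response, W718S/Y722S minus WT, called 223 of 13055 genes, 165 lower and 58 higher in the mutant, and 256 on the deposited values. The count was 354 without Dex replicate 1 of the mutant and 126 with the closest libraries averaged. Of the 223, 188 were called in WT, 182 with a smaller or opposite change in the mutant (65 of opposite sign by the estimate) and 6 with a larger one, and 35 were not called in WT. Among genes tested in both lines, 4 were called higher in W718S/Y722S and lower in WT, and 3 the reverse. Choosing genes by their WT call favours a smaller change here as well. Sgk1, Arrdc2, Spsb1 and Errfi1 rose less, with differences of -2.44 ± 0.07, -2.21 ± 0.13, -1.64 ± 0.13 and -1.42 ± 0.10 (log2 ± SE). The difference of Fabp4 was -2.85 ± 0.33, a value not past the threshold on the deposited values (adjusted p = 0.227). On the scale of size factors over all libraries, Fabp4 was at 41.7 ± 2.43 in W718S/Y722S and 5.67 ± 3.18 in WT in vehicle, and at 74.2 ± 15.8 and 75.1 ± 10.8 with Dex. Per1 differed by -0.15 ± 0.07 and did not pass (adjusted p = 0.382). Ccn2 had a larger log2 change, by 0.89 ± 0.18 (adjusted p = 0.00835), and did not differ past the threshold on the deposited values (adjusted p = 0.865). Klf9 had a larger log2 change by 0.29 ± 0.06 (adjusted p = 0.00893), and the decrease of Gdnf was smaller, by 0.66 ± 0.13. On that scale the levels of W718S/Y722S and WT in vehicle were 34.4 ± 5.37 and 75.3 ± 9.39 for Ccn2 and 760.4 ± 18.1 and 952 ± 52.0 for Klf9. With Dex they were 1266 ± 285 and 1442 ± 25.6, and 1428 ± 71.0 and 1456 ± 45.1. Sipa1l2, a GTPase-activating protein gene, went up in the mutant and not in WT, a difference of 0.53 ± 0.12 (adjusted p = 0.0152). Klhl35 (1.23 ± 0.30, adjusted p = 0.0270) and Prx (0.64 ± 0.14, adjusted p = 0.0152) differed upward too, though not past the threshold on the deposited values (adjusted p = 0.0727 and 0.526). The call of Klhl35, W718S/Y722S minus WT, ended without any 1 WT library other than WT vehicle replicate 3, and without vehicle replicate 5 or Dex replicate 2 of the mutant (0.0514 to 0.111). That of Prx, W718S/Y722S minus WT, ended without WT Dex replicate 2 (0.0589), and that of Sipa1l2, W718S/Y722S minus WT, without WT vehicle replicate 1, WT vehicle replicate 3 or WT Dex replicate 2 (0.0578 to 0.0644). Of 21 GR-induced genes the difference passed for 10 with a smaller rise and for Klf9 with a larger one.

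**Figure D2:**
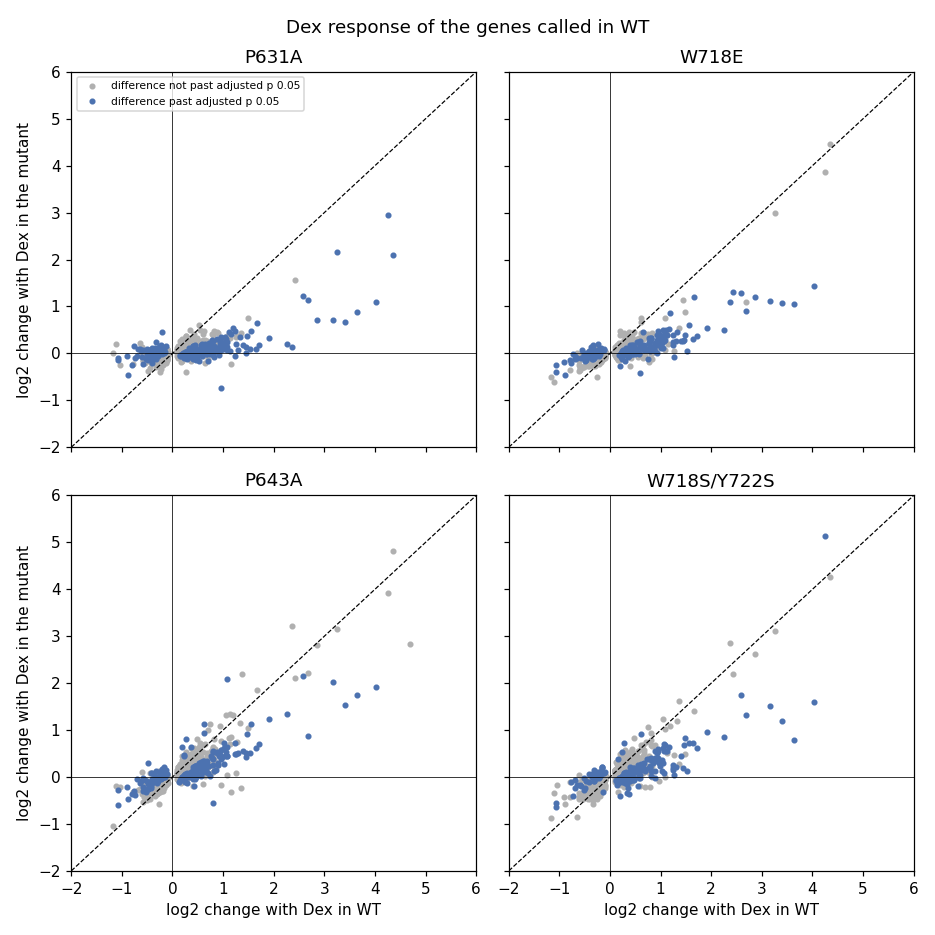
Log2 change with Dex in WT (x axis) and in each mutant (y axis) of the genes called in WT and also tested in that mutant. There is 1 point per gene, from n = 3 libraries per group (n = 5 in W718S/Y722S). Blue points passed the test of the difference at an adjusted p of 0.05, and the dashed line marks equal change. Genes called in WT that passed this test, drawn or not, numbered 241 in P631A, 219 in W718E, 186 in P643A and 188 in W718S/Y722S.

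Most genes called higher in a mutant were also called higher in WT, while in P643A and W718S/Y722S most genes called lower were not called lower in WT. A call missing in WT is not itself a difference from WT. The test of the difference called only 17 genes in P643A and 35 in W718S/Y722S that were not called in WT, both directions together. Of the genes tested in both lines and called higher, 24 of 25 in P631A, 60 of 60 in W718E, 247 of 329 in P643A and 188 of 313 in W718S/Y722S were also higher in WT. Independent lists of these sizes would share 0.981, 2.37, 13.1 and 12.4 genes. With the replicate block in W718E, 135 of its 165 genes called higher and 43 of its 120 called lower were shared, against 6.53 and 3.35 for independent lists. For genes called lower, the shared numbers without the block were 2 of 3, 4 of 6, 108 of 268 and 108 of 274, against 0.0836, 0.168, 7.52 and 7.76 for independent lists. These overlaps and the responder sets that follow used the calls of W718E without its block unless the block is named. The lines share no libraries, so these overlaps hold no shared controls. There were 16 genes higher in all 5 lines. They were Arrdc2, Bcl2l1, Ccn2, Foxred2, Klf9, Per1, Pik3r1, Sdc4, Sgk1, Sik1, Spsb1, Tead4, Trim24, Tsc22d3, Tsku and the predicted locus Gm6093. Among them Sik1 is a salt-inducible kinase, Pik3r1 a regulatory subunit of PI3 kinase, Sdc4 a heparan sulfate proteoglycan and Tead4 a transcription factor of the Hippo pathway. The single gene lower in all 5 was Dusp4. With the block in W718E there were 21 genes higher in all 5, the further ones being Ampd3, B3galnt2, Irs2, Itga10 and Vdr, and 2 lower, Dusp4 and Irs1. These genes were taken from the count of shared calls and not by the naming rule.

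To compare the size of the response without letting either line of a comparison choose the genes, each mutant was set against WT over genes called with the same sign in at least 2 of the 3 other mutants. Genes that rose formed sets of 200 for P631A, 199 for W718E, 61 for P643A and 68 for W718S/Y722S. Over them the median log2 change in WT and in the mutant was 0.44 and 0.13 for P631A, 0.44 and 0.17 for W718E, 0.98 and 0.61 for P643A, and 0.94 and 0.55 for W718S/Y722S. The median difference was -0.35 in P631A, -0.28 in W718E, -0.26 in P643A and -0.38 in W718S/Y722S. The mutant had the smaller change in 187, 178, 43 and 52 genes of these sets. The fry test of limma, adjusted over the 8 sets, gave an adjusted p of 5.17e-09 for P631A, W718E and P643A and an adjusted p of 8.08e-09 for W718S/Y722S. With the block in the calls of W718E, the sets held 114 genes for P643A and 136 for W718S/Y722S, and the median difference was -0.15 and -0.16 (adjusted p = 4.56e-07 and 9.11e-07). The sets of the first pair of mutants hold many more genes than those of the second pair, since a set depends on what the other mutants called, so the medians are not to be ranked across mutants.

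Genes that fell formed sets of 92 for P631A and W718E, with median log2 changes in WT and mutant of -0.23 and -0.06 for P631A and -0.23 and -0.10 for W718E. The median difference was 0.22 (adjusted p = 2.46e-06) and 0.15 (adjusted p = 1.84e-06). For P643A and W718S/Y722S the set held 6 genes each, and 35 and 49 with the block in the calls of W718E. The median difference over the larger sets was 0.010 in P643A (adjusted p = 0.00803) and 0.07 in W718S/Y722S (adjusted p = 0.0385). Over the 6 genes in P643A the median difference was -0.02 while the mean change moved from -0.51 in WT to -0.35 and the test pointed up (adjusted p = 0.000426), so the median and the test differ in sign. Over the 6 genes in W718S/Y722S the median difference was 0.10 (adjusted p = 0.0387), and on the deposited values 0.03 (adjusted p = 0.111). Over the 21 measured genes of the fixed GR-induced list the median difference was -0.90 in P631A, -0.64 in W718E, -0.44 in P643A and -0.42 in W718S/Y722S, and the largest adjusted p of the 4 tests was 5.06e-09. Among genes that rose in WT and had a called smaller change in the mutant, the vehicle level, with size factors over all libraries, made up at least 50% of the log2 difference in 32 of 182 in P631A, 40 of 158 in W718E, 42 of 119 in P643A and 43 of 142 in W718S/Y722S. The Dex level was below that of WT in 169, 134, 89 and 114 of them. Of the 8 genes in P643A and 5 in W718S/Y722S that rose in WT and had a called larger change, the vehicle level made up at least 50% in 6 and 4, and the Dex level was above that of WT in 3 and 1.

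**Figure D3:**
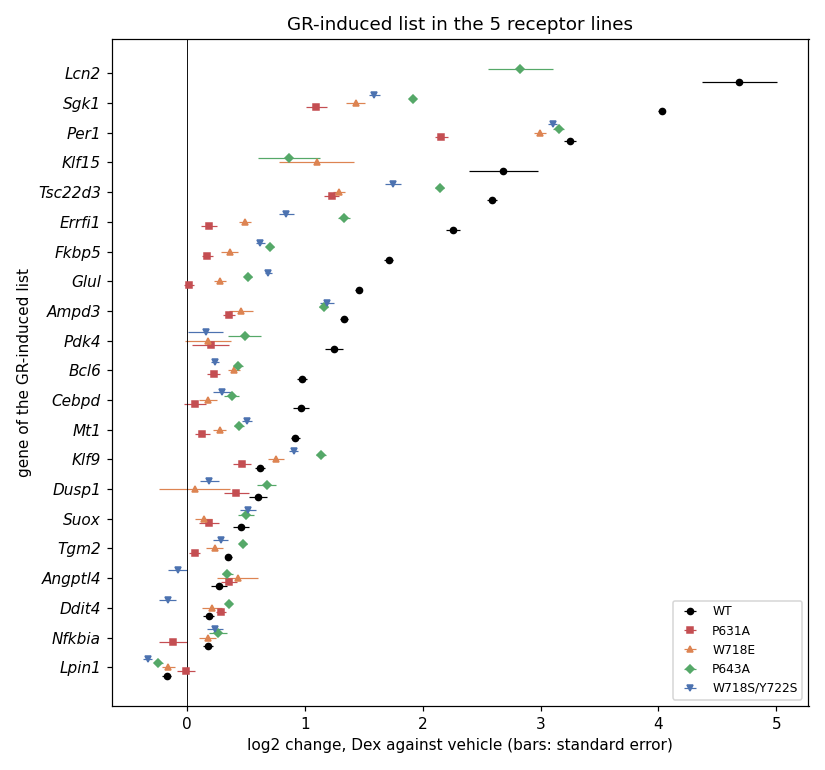
Log2 change with Dex against vehicle (x axis) of each measured member of the GR-induced list (y axis), with bars for the standard error, in WT (black circles) and the 4 mutants; n = 3 per group and n = 5 in W718S/Y722S. Sgk1 lay at 4.03 in WT and between 1.10 and 1.92 in the mutants, while Per1 lay at 3.25 in WT and between 2.16 and 3.16 in the mutants.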

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

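The tests of shrinkage, of missing and of partial exposure, of mixed RNA and of depth were chosen after the results were seen, while those of vehicle level, of the combined exposure or swap, of other splits and of shared calls were chosen before, although the bound that the Dex level had to pass in the test of vehicle level, 2 SD of the libraries, and the use of the blocked calls in it were set after. Single libraries were screened by the Dixon ratio in the groups with n = 5, over library totals and named genes. A ratio of 7 of 42 passed the critical value of 0.71, where chance alone passes about 1 in 20. In W718S/Y722S vehicle, replicate 5 had the highest total of reads (ratio 0.726) and replicate 1 the highest share of Rn45s (0.772). The other 5 ratios belonged to Dex replicate 1 of W718S/Y722S, which was highest for Ccn2 (0.788) and Phlda1 (0.794) and lowest for Thbs1 (0.801), Dusp4 (0.749) and Klhl35 (0.814). The differences of the Dex response from WT, at 252, 230, 203 and 223 genes, were also looked at again, as were the 8 responder sets. Their median differences were -0.35 and 0.22 in P631A, -0.28 and 0.15 in W718E, -0.26 and -0.024 in P643A, and -0.38 and 0.10 in W718S/Y722S, genes that rose first and genes that fell second.

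Each mutant had a smaller median rise than WT over genes induced in other mutants. Unequal shrinkage of the deposited tables does not enter the recovered counts, as far as their recovery holds. On these counts the median difference was -0.35, -0.28, -0.26 and -0.38 in P631A, W718E, P643A and W718S/Y722S, more than 2 SD of the libraries below 0. These are the values in which the smaller rise was seen, so they are not a separate test of shrinkage. A higher vehicle level as the whole cause would need most of the lost rise to lie in vehicle and Dex levels like those of WT. The median vehicle level made up -30.5% in P631A, -12.7% in W718E and 7.71% in P643A. The Dex level was below WT in 165 of 200, 153 of 199 and 44 of 61 genes, which argues against it for these sets as a whole. In W718S/Y722S the vehicle level made up 28.1% (38.5% by means), between the bounds set in advance, so the test leaves it open on that set, with a lower Dex level in 45 of 68 genes. Over the 136 genes found with the block in the calls of W718E, a set chosen after the results were seen, it made up -21.2%. The Dex level was lower in 93 of these 136, which argues, for those genes, against a higher vehicle level as the whole cause. It stays open as part of the cause and for single genes, since vehicle levels went both ways (higher than WT in 83, 90, 32 and 38 genes of the 4 sets) and the share was large for some, as in P643A for Sgk1 (75.3%) and Fkbp5 (88.2%), and small for others, as for Arrdc2 (6.77%). A lower receptor transcript stays open too, since Nr3c1 in vehicle was at 85.6, 72.8, 78.3 and 89.9% of WT in the 4 mutants, and receptor protein, hormone binding and the history of each line were not tested.

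Dex replicate 1 of W718S/Y722S stood apart from the other 4 Dex libraries in genes that do not depend on Dex as well as in some that do. Tpsab1, a mast cell tryptase, was at 1411 in it and at 25904 ± 608 in the other 4, against 25884 ± 1944 in vehicle, and Prl2c3, which shares reads with its near-identical copies Prl2c2 and Prl2c4, was at 476 against 3692 ± 301. The mean log2 change of the GR-induced list was 0.55 in it and 0.67 to 0.71 in the others, below them as set in advance for missing or partial exposure or a swap, while vehicle libraries lay between -0.02 and 0.03, which argues against no exposure or a vehicle label. Mixed RNA of another of the 5 lines would need the same own-line share for every marker, but over 14 markers higher in the line the shares spanned 41.0 to 46.4 percentage points, against 15.0 to 22.5 in the other Dex libraries, and at least 48.0 with the 1 marker lower in the line, just past the bound of 40 without it; the depth of 28.4 M reads lay within that of the other Dex libraries. Partial exposure stays open, since 29.4% of the induced genes changed more in it than in the others. Such exposure would leave Tpsab1 unexplained. It would also leave unexplained the larger changes in this library of Ccn2 (1469 against at most 1023 in the others), Thbs1 and Dusp4. Phlda1 went the other way, with a smaller fall. A culture of different composition may be a further, untested source.

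Of the genes called with Dex in P643A and not called in WT, some were also called in W718S/Y722S in the same direction. They were 25 of 79 genes that rose, where independent lists share 0.841 (Fisher's exact test, p = 5.54e-31), and 23 of 159 that fell, where they share 2.28 (Fisher's exact test, p = 4.96e-17). A response shared by these mutants was thus met by the test, but 23 of the 25 and 21 of the 23 had the same sign in WT. The difference from WT was itself called for 4 and 3 of them in P643A and in W718S/Y722S alike, so most may be genes that WT moved without passing.

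Other splits of the libraries were run for each count of genes. For Dex within WT (846 genes, 0 in the highest other split), P631A (28 and 37), W718E (66 and 1) and P643A (602 and 0), the 10 splits of 3 against 3 are too few for a share under 0.05; as many genes were called in 1, 2, 1 and 1 of them, the real split included. In W718E, if the numbers are taken to pair the libraries, the splits that part as many pairs called 0 genes. For W718S/Y722S the real split called 596 genes and the highest of the others 48, and only 1 of 100 splits, the real one, called as many. This argues against a random split of these libraries as the source of the count. The splits treat libraries as exchangeable, and the labels do not say that they are separate cultures, so chance between cultures is not excluded. For the differences from WT over 100 assignments the real one also called the most, with 252 against 60 genes in P631A, 230 against 1 in W718E, 203 against 2 in P643A and 223 against 104 in W718S/Y722S. The same limit holds there. In the other assignments a real difference in response also adds to the residual spread of its genes, which lowers their counts. Other assignments called up to 104 genes. Some may have kept many libraries under their own genotype, which was not examined, so the source of these calls stays open.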

How the results depend on the processing

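The 2-fold threshold on the recovered counts, the recovered counts with other pseudocounts, voom, the averaging of the closest libraries, the block in the calls of W718E behind sets and overlaps, and the size factors over all libraries were chosen after the data were seen. In all paragraphs the cause of a change between settings was not tested. With a 2-fold threshold, calls on the deposited values were 9 in WT, 0 in P631A, 1 in W718E, 6 in P643A and 4 in W718S/Y722S by limma (0 against 712 genes at an unadjusted p under 0.05 in P631A), and on the recovered counts 67, 6, 11, 32 and 22. The calls shared with WT were then 6, 10, 25 and 17 in the 4 mutants. Without a variance trend 5 genes were called in P631A, 42 in W718E and 387 in P643A, and the differences from WT were 159 in P631A, 152 in W718E and 115 in P643A. With all 34 libraries in 1 fit, 256 genes were called for Dex against vehicle in P643A and 1571 for Dex against vehicle in W718S/Y722S, and 99 differences in P643A. On the deposited values the differences were 357 in W718E and 312 in P643A. In W718S/Y722S, averaging the closest libraries gave 273 calls and 126 differences, and replicates 1 to 3 alone gave 213. Averaging was tried because some replicate pairs differed little from each other (chi-square per gene 1.39 to 1.69 in 4 pairs, 1 of them Dex replicates 2 and 3 of WT and 3 in W718S/Y722S). It gave 698 genes for Dex against vehicle in WT, and 39 in place of 65 for the difference of the Dex response, P631A minus WT, higher in mutant; the labels do not say whether they are separate cultures.

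With the replicate number as a block, W718E had 288 calls, 370 differences and 7 gene lists past the threshold. With these blocked calls W718E shared 178 calls with WT, 2 genes were lower in all 5 lines, and the responder sets held 114 and 35 genes for P643A and 136 and 49 for W718S/Y722S, genes that rose first. The median difference of the 35 genes was 0.010, reversed from -0.024. In P631A the block left 5 calls, but same-numbered libraries there had correlations of -0.49 to -0.17 and 0 of 3 matched best with their own number, so the numbers do not pair them. Correlations in WT, P643A and W718S/Y722S ranged from -0.14 to 0.20, 0.0028 to 0.16 and -0.21 to 0.14, with the own number best in 2 of 3, 2 of 3 and 1 of 5. In W718E the own number was best in 2 of 3 as well. With the block Irs1 and Ampd3, among others, gained a call in W718E. Apart from the lists given in the report for W718E, Irs1, Dusp4 and Rprl3 in P631A, Nr3c1 in W718S/Y722S and the difference of Klhl35 in W718S/Y722S, the block ended no other call that the naming rule picked. With an estimated correlation 2 gene lists passed in WT and 1 in each of P631A, W718E, P643A and W718S/Y722S, and with fry 2 passed in W718S/Y722S. With an estimated correlation and the block together, chosen after the data were seen, 1 list passed in each of WT, W718E and W718S/Y722S and 0 in P631A and P643A by camera. The responder set of genes that fell had a median difference of 0.12 in P643A when chosen by calls in WT, reversed from -0.024, and 0.035 in W718S/Y722S on the deposited values. With size factors over all libraries Nr3c1 in vehicle was 7065 in WT, 6045 in P631A, 5145 in W718E, 5533 in P643A and 6353 in W718S/Y722S.

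Leaving out each library in turn gave 625 to 1236 calls in WT, 14 to 49 in P631A, 28 to 76 in W718E, 453 to 564 in P643A and 412 to 971 in W718S/Y722S, with no change of sign among genes called in both fits. In P631A the count was 17 without vehicle replicate 2, 14 without vehicle replicate 3, 49 without Dex replicate 1 and 15 without Dex replicate 2. In W718E it was 28 without vehicle replicate 1 and 42 without Dex replicate 1, and in W718S/Y722S 971 without Dex replicate 1. Genes called ranged from 189 to 299 for the difference of the Dex response, P631A minus WT, from 177 to 242 for the difference of the Dex response, W718E minus WT, from 157 to 222 for the difference of the Dex response, P643A minus WT, and from 154 to 354 for the difference of the Dex response, W718S/Y722S minus WT, the highest without Dex replicate 1 of the mutant. Among named genes, values near 0 changed sign. The change of Nr3c1 in P631A was -0.00059 without vehicle replicate 2 (highest 0.029 without Dex replicate 1), that of Nr3c1 in W718E -0.00028, -0.0036, -0.0023 and -0.0057 without vehicle replicates 2 and 3 and Dex replicates 1 and 2 (highest 0.014 without Dex replicate 3), and that of Nr3c1 in P643A -0.0020 without vehicle replicate 2 (highest 0.0073 without vehicle replicate 1). On the deposited values the difference of Lims2, P643A minus WT, was -0.033 and that of Fabp4, P643A minus WT, 0.018. The fall of Nr3c1 in WT passed without Dex replicate 1 (adjusted p = 0.0197), with quantile normalisation (0.0117), without a variance trend (0.0292) and with all 34 libraries (0.0416). The count tests of edgeR and DESeq2 were planned for the case that reads could be recovered and were not run although they were recovered, because the deposited unit is log2.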

Other observations

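The lines differed in vehicle, apart from any response to Dex. Against WT, 32 genes in P631A, 57 in W718E, 69 in P643A and 111 in W718S/Y722S were at least 4-fold apart among 10325, 10334, 10311 and 10330 genes with a mean of at least 100. Fn1, fibronectin, was at 300435 ± 21579 in WT and 30760 ± 2703 in W718S/Y722S with size factors over all libraries, and Tpsab1 at 11.3 ± 0.677 and 31018 ± 2322. In P631A, W718E and P643A, Fn1 was at 100563 ± 5427, 74277 ± 3183 and 71699 ± 1443, so WT lay above every mutant. Tpsab1 in these lines was at 50.8 ± 1.66, 47.9 ± 4.27 and 129 ± 16.5, so W718S/Y722S lay above every other line. Malat1, a nuclear long noncoding RNA, took a median of 5.19% of exon counts in WT libraries and 1.19 to 1.64% in the mutant lines. Rn45s took a median of 10.4% in WT libraries and 14.6 to 16.6% in the mutant lines. No test of these levels was made.

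Some of the genes called in both P643A and W718S/Y722S and not in WT are named here, chosen after their values were seen and without a test for enrichment. Those that rose included Adm, a vasodilator peptide gene, Dusp7, a MAP kinase phosphatase, Snai1, a repressor of epithelial genes, and Timp2, an inhibitor of matrix proteases. Those that fell included Cited2, a coregulator of CBP, Klf5, Klf7, Snai2 and Nr1d1. For Cited2 the difference from WT was called in both mutants, and its log2 change was 0.02 in WT, -0.29 in P643A and -0.34 in W718S/Y722S. Klf9 was the gene of the GR-induced list with a larger rise than WT in both, by 0.52 ± 0.06 and 0.29 ± 0.06, but with size factors over all libraries its Dex level was not above that of WT (1251 ± 11.3 and 1428 ± 71.0 against 1456 ± 45.1), and its vehicle level was lower (571 ± 7.11 and 760.4 ± 18.1 against 952 ± 52.0). A weak WT response below the threshold may account for most of the shared calls, since 23 of the 25 rises and 21 of the 23 falls had the sign of WT.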
